A study of Mus musculus with 6 samples.

How the data were processed

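Messenger RNA levels were measured on 6 Affymetrix mouse exon arrays (Mouse Exon 1.0 ST, per the header of the probe annotation), 1 array per sample. Per the labels' protocols, m-Citrin neurons were picked by hand with a glass pipette from acutely dissociated visual cortex, total RNA was extracted with the PicoPure kit, and biotinylated cRNA was made by T7 in vitro transcription in 2 rounds from 0.3 to 1 ng of RNA. Such amplification starts at the 3' end of transcripts and can add variation between samples, which was not measured here. The labels place 3 arrays in the deprived and 3 in the non-deprived group and number them 1 to 3 in each. The letter after the number in the labels differs between the groups, so hemisphere side, if that is what it marks, cannot be separated from deprivation.

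The deposited table holds 1 log2 expression value per transcript cluster and array, as the authors summarised it, with 23331 clusters. That the scale is log2 was read from the values, which run from 0.584 to 13.6; background correction, normalization between arrays and summarization are not given in the sources used here. The genome build mm9 is named in the submitters' processing notes. Array medians over all clusters were 5.35, 5.15 and 5.16 for non-deprived arrays 1 to 3 and 5.28, 5.29 and 5.37 for deprived arrays 1 to 3, so centring of each array at this level was not complete. The values were used without further scaling. No measure of background or detection was used here, so no gene was left out as undetected, and values near the bottom of the range have no known floor. The number of arrays limits the precision.

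Clusters were named through the platform annotation. Of the 23331 clusters, 14995 had 1 gene symbol, 1019 had several and were not named, and 7317 (31.4%) had no entry and are unnamed here; their mean values had a median of 4.41, against 5.63 for the named genes. Symbols were checked through the Entrez identifier against RefSeq gene names of assembly GRCm38.p6, which found 14940 of the clusters and changed 0 symbols. For 135 genes with several clusters, the cluster with the highest mean over all 6 arrays was used; in 54 of them the clusters disagreed in direction. This left 14859 genes. Several genes of the lists, among them the marker Xist, had no cluster with a symbol of their own and were not analysed here.

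The groups were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the variance), with the group as the sole term, and Benjamini-Hochberg adjustment over the 14859 genes at a threshold of 0.05. All tests were two-sided. Differences are deprived minus non-deprived on the log2 scale, and intervals are 95% intervals from the moderated fit. Before the data were examined, 34 gene lists were fixed, covering activity-regulated genes, receptors, channels, synaptic and plasticity genes, metabolism, stress, markers of cortical cell types and sex-linked genes. A list needed at least 5 measured genes, and 31 were tested. The metabotropic glutamate receptors (4 measured) and blood genes (2 measured) had too few, and the sex-linked genes served to compare arrays. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists, with an estimated correlation and with fry as alternatives. Fry's directional p asks whether the genes of a list move one way on balance and does not compare the list with other genes. The median of each list was also placed among 10000 random lists of the same size matched on mean expression in 20 bins.

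The genes named in the text follow a rule fixed before the data were examined. With fewer than 20 genes past the threshold, they are every gene that passed (0 here) and the 10 with the smallest unadjusted p in each direction, leaving out provisional symbols; Fos, Egr1, Arc, Npas4, Nr4a1 and Bdnf; up to 3 members of each tested list with the smallest p; and the markers Rorb, Slc17a7, Gad1, Gfap, Mbp and Xist. Other genes were chosen after their values were seen, and the text says so where they appear.

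The fit and the list tests were first tested on simulated data for this comparison, with 14859 genes and 200 of them changed, in 5 runs. Of the changed genes, 17.2% were called at a log2 difference of 1, 57.2% at 2, 71.2% at 3 and 84% at 4, with a mean of 7.2 false calls per run. An immediate-early list lowered by 1 was called in 100% of the runs, with a mean of 0.2 other lists called per run. The simulated genes varied independently of each other and with the same spread on every array. In the data, camera's estimated correlation for this list was 0.157, and non-deprived arrays 2 and 3 stood apart from the rest. The simulated rates may therefore not hold for these data.

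The alternatives fixed before the data were examined were the replicate number as a block, quantile normalization, median centring, restriction to genes at or above the median or the 25th percentile of mean expression, the mean over the clusters of a gene, array weights, eBayes without trend or with robust fitting, every cluster tested on its own, a threshold of 0.1, and leaving out each array in turn. Leaving out non-deprived arrays 2 and 3 together was added after seeing that they stand apart; it leaves 1 non-deprived array, which is assumed to vary like the deprived arrays. All 10 splits of the 6 arrays into 3 and 3 were fitted in the same way. The labels do not say that arrays of the same number belong together. The deviations of same-numbered arrays from their group means did not correlate, so they were treated as unpaired. These deviations include the departures of non-deprived arrays 2 and 3, which could hide a pairing. The level of the Y-linked gene Eif2s3y did follow the numbers, so a pairing is not excluded.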

Results

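Gene expression was profiled in star pyramid neurons, an excitatory cell type of layer 4 of the mouse visual cortex, after monocular deprivation. The animals received tetrodotoxin (TTX), which blocks voltage-gated sodium channels and so silences the injected eye, at postnatal day 12 to 13 and again at postnatal day 13 to 14. Fluorescent (m-Citrin) neurons were sorted by hand at postnatal day 14 from deprived and non-deprived hemispheres. From 0.3 to 1 ng of total RNA was amplified in 2 rounds and hybridised to exon arrays. The data hold 6 arrays, 3 of the deprived and 3 of the non-deprived group, with a log2 expression value for each of 23331 transcript clusters, of which 14859 named genes were tested. The number of arrays limits the precision: the median standard error of a log2 difference between the groups was 0.312. The labels do not say whether the 3 samples of a group came from separate animals. The Y-linked gene Eif2s3y was at 2.81 in non-deprived array 3 and at 2.33 in deprived array 3. On arrays 1 and 2 of both groups it was between 6.76 and 8.51. Kdm5d, also Y-linked, was lowest in array 3 of both groups too. These values argue against a single animal as the source of all 3 samples of a group. The p-values measure only the spread between these samples, part of which may be technical.

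Non-deprived arrays 2 and 3 stood apart from the other 4. Their 75th percentiles over the named genes were 6.43 and 6.55, against 7.08 in non-deprived array 1 and 7.01, 7.15 and 7.11 in the deprived arrays. They held 2769 and 2900 named genes above a log2 value of 7, where the other 4 arrays held between 3727 and 3960. Non-deprived array 2 correlated with the other 5 arrays at a mean Pearson r of 0.863 across genes and non-deprived array 3 at 0.886, compared with 0.906 to 0.916 for the rest. The leading principal component, with 38.2% of the variance, separated these arrays (scores of 79.5 and 33.7) from the other 4 (-34.6 to -20.7). They did not depart in the same way: on the next component, with 22.7% of the variance, they lay at opposite ends (39.5 and -67.8), and their r with each other was 0.861.

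**Figure D1:**
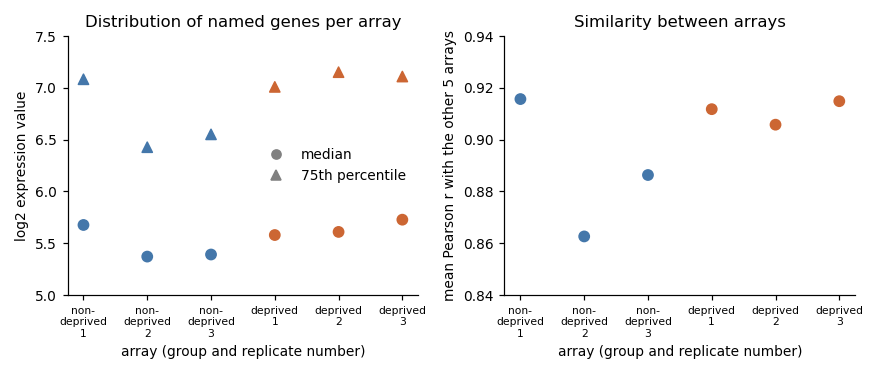
Left, the median (circles) and 75th percentile (triangles) of the log2 expression values of the named genes on each array; right, the mean Pearson r of each array with the other 5 arrays, across genes. Blue marks the non-deprived and orange the deprived arrays; non-deprived arrays 2 and 3 have the lowest 75th percentiles, 6.43 and 6.55, and the lowest mean r, 0.863 and 0.886.

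The comparison of deprived with non-deprived hemispheres asks which transcripts of these neurons change when the eye that drives them is silenced. No single gene passed the threshold, and the classical activity markers differed by less than the spread between arrays. The groups of genes that were higher in the deprived arrays were markers of excitatory neurons, with Slc17a7, the vesicular glutamate transporter VGLUT1, at 10.16 ± 0.22 against 9.13 ± 0.27 (mean ± SD, n = 3 arrays per group), calcium and sodium channels, postsynaptic scaffold proteins, axon guidance molecules and genes of the endoplasmic reticulum stress response. These 6 of 31 gene lists passed camera with its preset correlation, and none of them did with an estimated correlation (adjusted p = 0.761 for each, unadjusted p from 0.0249 to 0.238). The estimated correlation was -0.0495 for the excitatory markers and 0.13 to 0.28 for the other lists that passed. When non-deprived arrays 2 and 3 were left out together, the excitatory markers alone passed. Leaving out 1 array moved the medians of 29 of the 31 lists and the differences of 52 of 119 named genes by over 1.5 times. A range given with the median of a list spans its values when each array was left out in turn. For single genes such values are printed beside some of those that moved, so a gene without one is not thereby stable.

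Limma called 0 of the 14859 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.689. At an unadjusted p under 0.05 there were 775 genes, where 742.95 were expected with no effect. Of these, 566 were higher and 209 lower in the deprived arrays, so that 73.0% were higher. That share was 58.2% after median centring of the arrays, 59.8% after quantile normalization and 36.0% without non-deprived arrays 2 and 3 (219 higher, 390 lower). Leaving out non-deprived array 1 gave 1434 higher and 416 lower genes. In 1535 genes (10.3%) the values of the groups did not overlap, where chance gives 10%. Of these, 936 were higher and 599 lower in the deprived arrays. Genes named below for a small p, or after their values were seen, were likelier to separate in this way. Their separation is therefore no added evidence of a difference.

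The named genes with the smallest p in the upward direction did not pass the threshold (adjusted p = 0.689 for each). Pycard, the inflammasome adaptor ASC (transcript cluster 6971415), was at 6.04 ± 0.32 in the deprived and 4.24 ± 0.26 in the non-deprived arrays (mean ± SD, n = 3 each), a log2 difference of 1.80 ± 0.23 (SE). Hsdl2, a peroxisomal dehydrogenase-like protein (cluster 6913901), differed by 2.50 ± 0.34, and Tbrg1 (cluster 6994710), a growth regulator that responds to TGF-beta, by 2.64 ± 0.41. A pair of adaptor-complex subunits of vesicle traffic were among these genes, Ap3m1 with a difference of 1.51 ± 0.21 and Ap4m1 with 1.13 ± 0.16. The remaining 5 were Myadml2 (1.66), Zfp35 (1.59), Pggt1b (1.70), the kinase Map3k2 (1.48) and Nubpl, an assembly factor of respiratory complex I (3.22).

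In the downward direction, Cox7b, a small subunit of cytochrome c oxidase (cluster 7013183), was at 5.10 ± 0.88 in the deprived and 8.09 ± 0.14 in the non-deprived arrays (mean ± SD, n = 3 each), a log2 difference of -2.99 ± 0.47 (SE) with an adjusted p of 0.689 in limma. Vps4b, an ATPase of the endosomal sorting machinery, differed by -1.60 ± 0.34 from a non-deprived mean of 9.62, and Mrpl51, a mitochondrial ribosomal protein, by -2.59 ± 0.55 from 5.62. Swt1 differed by -1.19, Eddm3b by -0.62 and Igbp1b by -0.71. The other 4 of these 10 genes, the olfactory receptors Olfr849, Olfr1314 and Olfr521 and the vomeronasal receptor V1ra8, had non-deprived means between 2.46 and 3.21, in values with no known floor. None of the 10 passed (adjusted p of 0.689 for Cox7b and V1ra8 and 0.856 for the other 8).

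Among immediate-early genes, which neurons transcribe within minutes of activity, 28 were measured, and 21 of them were higher and 7 lower in the deprived arrays. The list did not pass camera (median log2 difference 0.20, range 0.097 to 0.268, adjusted p = 0.209), but passed upward when deprived array 1 was left out (median 0.27, adjusted p = 0.0271), and 0 members passed over all genes or adjusted over the list alone. Fos was at 6.72 ± 0.58 in the deprived and 6.98 ± 0.89 in the non-deprived arrays, a difference of -0.26 with a 95% interval from -1.57 to 1.06. Its sign turned without non-deprived array 2 (0.255), without deprived array 1 (0.049) and without non-deprived arrays 2 and 3 (0.33). For Arc, whose product acts at synapses, the difference was -0.07 (-0.996 to 0.851), and 0.122 without non-deprived array 1 and 0.159 without deprived array 2. Egr1 differed by 0.08 (-0.69 to 0.85) and Nr4a1 by 0.22 (-0.99 to 1.42), and both signs turned after quantile normalization, to -0.21 and -0.07. The sign of Egr1 turned after median centring too, to -0.02, and leaving out 1 array gave -0.0033 to 0.18 for Egr1 and -0.28 to 0.63 for Nr4a1. Npas4 was at 6.20, 5.67 and 9.56 in the non-deprived arrays 1, 2 and 3 and between 8.17 and 9.13 in the deprived arrays, so that its difference of 1.48 ± 1.02 (SE) was within the spread of the non-deprived group. It was 0.74 without non-deprived array 2 and 2.69 without non-deprived array 3. The members with the smallest p were Nr4a2 (1.64), Crem (0.37) and Nr4a3 (0.47), each with an adjusted p of 0.856 in limma. Nr4a2 was at 7.88 and 7.17 in deprived arrays 2 and 3 but at 5.12 in deprived array 1, within the non-deprived values of 4.86 to 5.28.

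**Figure D2:**
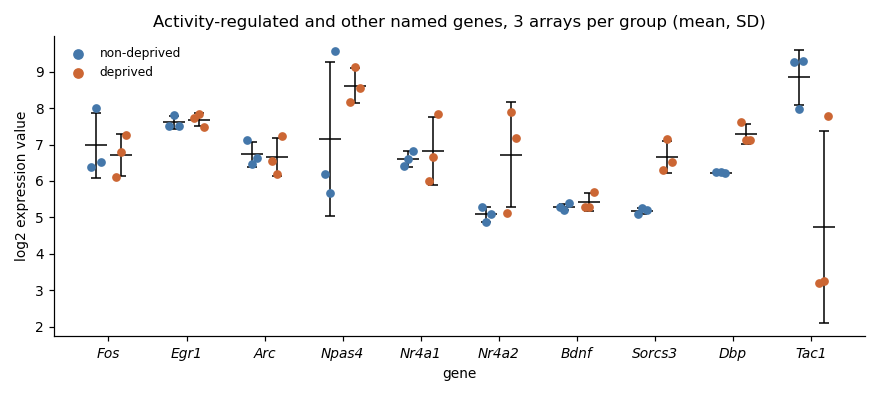
Log2 expression values of 8 activity-regulated genes and of Dbp and Tac1 on each of the 6 arrays, with non-deprived arrays in blue and deprived arrays in orange; horizontal lines are means and bars are SDs of 3 arrays. Fos, Egr1 and Arc overlap between the groups, whereas Sorcs3 and Dbp are higher in each deprived array than in every non-deprived array and Tac1 is lower.

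Late activity-regulated effector genes were measured at 27 members, 16 higher and 11 lower (median 0.13, range 0.0495 to 0.214, camera adjusted p = 0.679; the median was -0.11 after quantile normalization). One member passed when adjusted over the list alone (1 gene, against 0 over all genes), Sorcs3, a sorting receptor of the postsynaptic density. It was at 6.65 ± 0.44 in the deprived and 5.19 ± 0.08 in the non-deprived arrays (mean ± SD, n = 3 each). Its log2 difference of 1.47 ± 0.28 (SE) ranged from 1.22 to 1.64 when each array was left out in turn. Tac1, the precursor of substance P, was at 9.26, 7.97 and 9.30 in the non-deprived arrays and at 3.20, 3.25 and 7.79 in the deprived arrays, a difference of -4.10 ± 1.26 (SE), unadjusted p = 0.0152 in limma. Rasgrp1 differed by 0.82. Bdnf, the neurotrophin, differed by 0.14 (95% interval -0.32 to 0.60), and by -0.00017 without deprived array 3. Feedback inhibitors of MAP kinase signalling (12 genes) had a median of 0.00383 (range -0.14 to 0.16) and an adjusted p of 0.929, with signs that turned under quantile normalization and median centring; Errfi1, Spred2 and Spred1 differed by 0.64, 0.44 and 0.32, the last by 0.16 without deprived array 2. CREB, calcineurin and CaM kinase signalling genes (23) had a median of 0.17 (range 0.14 to 0.25, adjusted p = 0.250; -0.0096 after quantile normalization), with Camk1d at 0.84, Camk2d at 0.95 and Crtc1 at 0.93. No member of these 2 lists passed over all genes or adjusted over the list alone.

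Calcium channel genes were higher in the deprived arrays in 13 of 13 measured members (median log2 difference 0.67, range 0.24 to 0.92, camera adjusted p = 0.0062). The call was lost with an estimated correlation (adjusted p = 0.761), and fry's adjusted directional p was 0.420. Cacnb1, an auxiliary subunit, was at 8.25 ± 0.08 in the deprived and 7.33 ± 0.17 in the non-deprived arrays (mean ± SD, n = 3 each), and Cacna1e and Cacna1d, pore-forming subunits, differed by 1.26 and 0.83 (0.71 and 0.50 without non-deprived array 2). The sodium channel list, which also holds accessory and anchoring proteins, was higher in 10 of 11 members (median 0.43, range 0.34 to 0.98, adjusted p = 0.0364; adjusted p = 0.761 with an estimated correlation). Its members with the smallest p were the beta subunit Scn2b (2.10), the axon initial segment scaffold Ank3 (0.89) and Fgf13 (1.69). Ank3 was at 0.60 without non-deprived array 2 and Fgf13 at 0.65 without non-deprived array 3. Postsynaptic scaffold genes were higher in 19 of 23 members (median 0.59, range 0.33 to 0.96). Camera's adjusted p was 0.0062, and 0.761 with an estimated correlation. Dlg4, which encodes PSD-95, was at 10.36 ± 0.12 in the deprived and 9.66 ± 0.39 in the non-deprived arrays. Lrrtm1 differed by 1.13 (0.72 without non-deprived array 2) and Sipa1l1 by 1.03.

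Non-deprived array 2 was the lowest array in each of these 3 lists. The median level of the calcium channel genes was 7.73 in non-deprived array 1, 6.56 and 7.45 in arrays 2 and 3, and between 7.89 and 8.26 in the deprived arrays. For the scaffold genes it was 8.32 in non-deprived array 1, 7.04 and 7.44 in arrays 2 and 3, and 7.99 to 8.29 in the deprived arrays, and for the sodium channel list 8.62, 7.504 and 8.284 against 8.27 to 9.07. With arrays 2 and 3 of the non-deprived group left out together, the list medians were 0.17 for calcium channels, 0.16 for sodium channels and -0.05 for scaffold genes, and none passed (adjusted p = 0.801, 0.985 and 0.985). Leaving out non-deprived array 2 alone also ended all 3 calls, with medians of 0.24 for calcium channels, 0.34 for sodium channels and 0.33 for scaffold genes. The sodium channel call ended as well without non-deprived array 3, deprived array 1 or deprived array 3, although its median did not shrink (0.46, 0.49 and 0.68), and over genes at or above the 25th percentile of mean expression (median 0.43, adjusted p = 0.108). After quantile normalization the scaffold call ended (median 0.37, adjusted p = 0.0541), whereas calcium channels (0.38, adjusted p = 0.0237) and sodium channels (0.32, adjusted p = 0.0275) passed. After median centring, which moves all genes of an array alike, all 3 passed, with medians of 0.57 for calcium channels, 0.50 for scaffold genes and 0.33 for sodium channels (adjusted p = 0.0035, 0.0035 and 0.0129). Camera compares a list with the other genes, so a shift common to all genes could hardly end a call. A pass after median centring therefore adds little, here and for the lists below. Over genes at or above the median mean all 3 calls ended (adjusted p of 0.0925 to 0.141), while the medians were 0.67 for calcium channels, 0.59 for scaffold genes and 0.89 for sodium channels. The genes they were compared with had changed, here and for the lists below. The median difference of all genes tested was 0.05 in the main fit. It was 0.113 over genes at or above the 25th percentile and 0.227 over those at or above the median mean.

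Axon guidance genes had the smallest p of all lists, with 34 of 41 members higher (median 0.37, range 0.27 to 0.64, camera adjusted p = 0.00104; adjusted p = 0.761 with an estimated correlation). The list also passed after quantile normalization (0.29, adjusted p = 0.0035) and median centring (0.27, adjusted p = 0.00047). Slit2, a secreted guidance cue, was at 6.91 ± 0.18 in the deprived and 5.69 ± 0.48 in the non-deprived arrays (mean ± SD, n = 3 each). Efnb2, an ephrin ligand, differed by 2.52 ± 0.82 (SE), and by 1.63 without non-deprived array 3. Sema4g differed by 0.58 ± 0.20 (SE). The median of the list was -0.02 without non-deprived arrays 2 and 3 (adjusted p = 0.985). Genes of the endoplasmic reticulum and integrated stress response were higher in 17 of 19 members (median 0.48, range 0.11 to 0.62, adjusted p = 0.0364; adjusted p = 0.761 with an estimated correlation). Hspa5, the chaperone BiP, differed by 0.52 (0.32 without non-deprived array 3), Herpud1 by 0.72 and Sesn2 by 0.85. Their median level was 7.82 in non-deprived array 1, 6.54 and 6.64 in arrays 2 and 3, and 7.33 to 7.60 in the deprived arrays, and the list's median difference without arrays 2 and 3 was 0.12 (adjusted p = 0.985). Leaving out non-deprived array 2 alone ended both calls, with medians of 0.27 for axon guidance (adjusted p = 0.105) and 0.42 for the stress genes (adjusted p = 0.186). The stress gene call also ended without non-deprived array 3 (median 0.11), deprived array 2 (0.43) or deprived array 3 (0.53), with the replicate number as a block (0.48, adjusted p = 0.0566) and after quantile normalization (0.26, adjusted p = 0.0909). After median centring it passed (0.38, adjusted p = 0.0278). It ended over genes at or above the 25th percentile and the median of mean expression too, where the medians were 0.48 in both cases (adjusted p = 0.132 and 0.355). In each of the 6 lists that passed, 0 members passed over all genes and 0 adjusted over the list alone.

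Markers of excitatory neurons were higher in 9 of 10 measured members (median 0.53, range 0.37 to 0.72, camera adjusted p = 0.0062). With an estimated correlation camera's unadjusted p was 0.0249 and the adjusted p = 0.761, and fry gave an adjusted p of 0.0747. The estimated correlation was -0.0495, so the larger p did not come from genes of this list varying together. Slc17a7 differed by 1.02 ± 0.26 (SE), Slc17a6, which encodes VGLUT2, by 1.67 ± 0.52, and Nell2 by 0.71 ± 0.24, and each of these was higher in all 3 deprived than in all 3 non-deprived arrays. Without non-deprived arrays 2 and 3 their differences were 0.72, 0.99 and 0.29, the list median was 0.36 and its adjusted p was 0.0027, which rests on non-deprived array 1 alone with the spread of the deprived arrays. The list passed after quantile normalization (0.47, adjusted p = 0.0035) and median centring (0.44, adjusted p = 0.0048). It no longer passed when deprived array 3 was left out (median 0.47, adjusted p = 0.0532) or over genes at or above the median mean (median 0.71, adjusted p = 0.0925). Layer 4 markers were higher in 10 of 11 members (median 0.30, range 0.17 to 0.37, adjusted p = 0.204), with Cux1 at 0.94, Cux2 at 0.38 and Tmem215 at 0.46 (0.17 without non-deprived array 3); Rorb, a transcription factor of layer 4 neurons, was at 8.11 ± 0.32 in the deprived and 7.70 ± 0.87 in the non-deprived arrays. Its difference of 0.40 turned to -0.034 without non-deprived array 3. Layer 2/3 markers had a median of 0.44 (6 of 10 higher, adjusted p = 0.250). It was 0.61 without non-deprived array 1 (adjusted p = 0.0393), 0.12 without non-deprived array 2 (adjusted p = 0.888) and -0.15 without non-deprived arrays 2 and 3. Its members with the smallest p were Lamp5 at 1.95, Matn2 at 0.88 (0.49 without non-deprived array 2) and Rasgrf2 at 1.00. Layer 5/6 markers had a median of 0.31 (10 of 16 higher, adjusted p = 0.645), which was 0.0495 without non-deprived array 3 and 0.41 without deprived array 2, with Nr4a2 at 1.64, Tle4 at 0.50 (0.26 without non-deprived array 3) and Ldb2 at 1.19 (0.064 without non-deprived array 2).

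**Figure D3:**
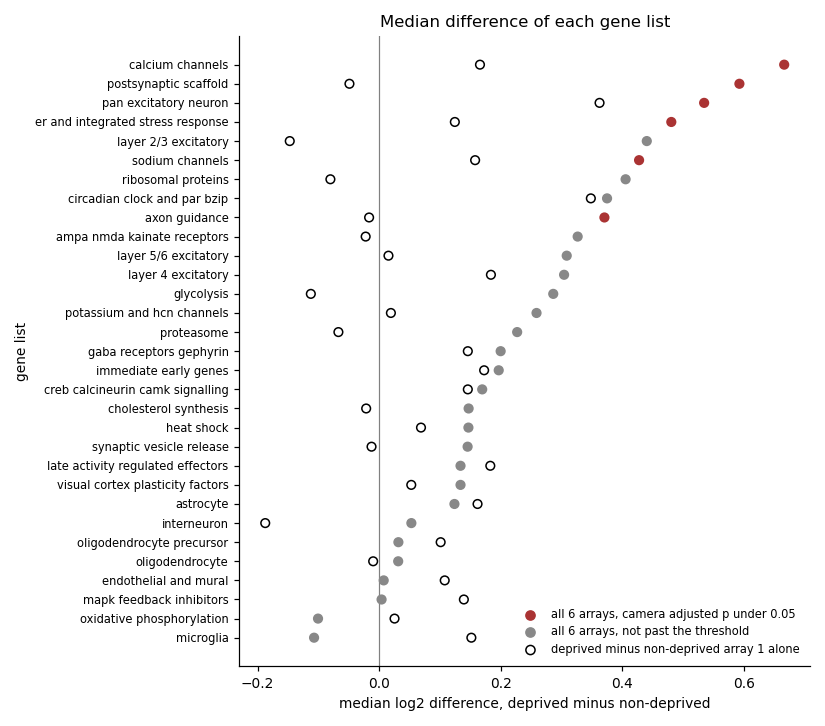
Median log2 difference, deprived minus non-deprived, of each of the 31 tested gene lists (one row each). Filled points use all 6 arrays (red, camera adjusted p under 0.05; grey, not) and open points use non-deprived array 1 as the sole non-deprived array; calcium channels move from 0.67 to 0.17 and postsynaptic scaffold genes from 0.59 to -0.05, whereas excitatory neuron markers move from 0.53 to 0.36.

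Markers of other cell types did not pass in any list. Interneuron markers had a median difference of 0.05 (range 0.0104 to 0.24, 10 of 18 higher, adjusted p = 0.900; -0.02 after quantile normalization and -0.04 after median centring), and the members with the smallest p were Tac1 (-4.10), Pvalb (1.53) and Gad2 (1.503). Without non-deprived array 2 these were -4.54, 0.76 and 0.94, and Gad1, at 0.67 with all arrays, was 0.20. The median level of this list was 6.89 in non-deprived array 1, 6.02 and 6.34 in arrays 2 and 3, and 6.09 to 7.23 in the deprived arrays, and without non-deprived arrays 2 and 3 its median difference was -0.19, with Gad1 at -0.48 and Gad2 at -0.38. Astrocyte markers had a median of 0.12 (range -0.019 to 0.28, 10 of 16 higher, adjusted p = 0.679; -0.04 after quantile normalization), with Clu at 1.16, Gja1 at 0.47 (0.27 without deprived array 1) and Gfap at -0.24. Oligodendrocyte markers had a median of 0.03 (range -0.047 to 0.089, 8 of 14 higher, adjusted p = 0.967; -0.04 after quantile normalization and -0.07 after median centring), with Mbp at 0.17 (-0.107 without deprived array 1), Cnp at 0.56, Ugt8a at 0.34 and Gjc3 at -0.24. Their precursors' markers had a median of 0.03 (range -0.044 to 0.11, 5 of 8 higher, adjusted p = 0.679; -0.14 after quantile normalization and -0.07 after median centring), with Vcan at 0.80 (0.26 without deprived array 1), Neu4 at -0.25 and Pdgfra at -0.19 (-0.13 and -0.097 without non-deprived array 2). Microglial markers had a median of -0.11 (range -0.18 to -0.0088, 9 of 16 lower, adjusted p = 0.579), with Aif1 at 0.78, Fcer1g at -0.39 and C1qc at 0.26. Endothelial and mural markers had a median of 0.0073 (range -0.05 to 0.041, 9 of 17 higher, adjusted p = 0.609; -0.09 after quantile normalization and -0.09 after median centring), with Pecam1 at 0.32, Pltp at -0.70 (-0.40 without non-deprived array 1) and Itm2a at 1.24 (0.22 without deprived array 3, where it was at 6.52 against 3.56 and 3.31 in the other deprived arrays). For the oligodendrocyte, precursor and endothelial lists camera's direction was downward while the median was above 0.

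The remaining synaptic and plasticity lists did not pass. AMPA, NMDA and kainate receptor genes had a median of 0.33 (range 0.23 to 0.56, 16 of 19 higher, camera adjusted p = 0.0612). Grin2a differed by 0.95, Grik2 by 1.43 and Grin2b by 1.61. Without non-deprived array 2, Grin2a was at 0.62 and Grin2b at 0.71. This list passed after median centring (median 0.23, adjusted p = 0.0380), with array weights (0.41, adjusted p = 0.0419) and without non-deprived array 1 (0.56, adjusted p = 0.0057), whereas without non-deprived arrays 2 and 3 its median was -0.02 and Grin2b differed by -0.07. GABA receptor genes with gephyrin had a median of 0.20 (range -0.034 to 0.44, 6 of 9 higher, camera adjusted p = 0.645). Gabra5 differed by 1.53, Gabbr1 by 0.66 and Gabrb2 by -0.56. Without non-deprived array 2, Gabra5 was at 0.93 and Gabrb2 at -0.31. Potassium and HCN channel genes were higher in 35 of 44 members (median 0.26, range 0.091 to 0.44, adjusted p = 0.0524). Kcnn2, a small-conductance calcium-activated channel, differed by 1.498 ± 0.372 (SE) and Kcna4, an A-type channel, by 1.26 ± 0.34. Kcnab2 differed by 1.63, and by 1.04 without non-deprived array 3. This list passed after median centring (adjusted p = 0.0278), with the mean over the clusters of a gene (0.0478), with array weights (0.0433), without non-deprived array 1 (0.0176) and without deprived array 1 (0.0470), and had a median of 0.02 without non-deprived arrays 2 and 3. Synaptic vesicle release genes had a median of 0.15 (range -0.005 to 0.37, 21 of 29 higher, adjusted p = 0.250), with Cplx2 at 1.57, Syt5 at 1.34 and Sv2b at 1.43 (0.75 without non-deprived array 2). Visual cortex plasticity factors had a median of 0.13 (range 0.006 to 0.18, 16 of 27 higher, adjusted p = 0.645; -0.05 after quantile normalization), with Ncan at 1.13, Ntrk3 at 0.72 and Igf1r at 0.83. In each of these 5 lists 0 members passed over all genes and 0 adjusted over the list alone, and the same held for the 10 cell type lists.

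Of the metabolic and stress lists, oxidative phosphorylation was the one in which lower members were more frequent, 29 of 50 (median -0.10, camera adjusted p = 0.250). Its median lay below those of all 10000 random lists matched on mean expression, a measure that takes genes as independent. Over genes at or above the median mean expression it passed downward (median -0.10, adjusted p = 0.0135), and without non-deprived array 2 its median was 0.10. One member (1 gene) passed adjusted over the list alone, Cox7b, with 0 over all genes, and this adjustment again leaves the number of lists out. The small subunits Ndufb7 and Cox6a1 differed by -1.23 ± 0.35 and -0.89 ± 0.27 (SE), and both were lower in all 3 deprived than in all 3 non-deprived arrays. Glycolysis genes had a median of 0.29 (12 of 16 higher, adjusted p = 0.226). It was 0.51 without non-deprived array 1 (adjusted p = 0.0393), 0.12 without non-deprived array 2 (adjusted p = 0.742) and -0.11 without non-deprived arrays 2 and 3. The members with the smallest p were the transporters Slc16a1 at 0.88, Slc2a3 at 1.57 and Slc2a1 at 0.80 (0.44 without deprived array 3). Cholesterol synthesis genes had a median of 0.15 (range 0.023 to 0.395, 12 of 18 higher, adjusted p = 0.516), with Pmvk at 1.43, Cyp51 at 1.06 and Lss at 1.06 (0.49 without deprived array 2). Ribosomal protein genes, of which 16 of the 78 listed were measured, had a median of 0.41 (10 higher, adjusted p = 0.645), above 97.87% of the matched random lists. The median was -0.036 without non-deprived array 3 and -0.0803 without non-deprived arrays 2 and 3. Members differed in direction, with Rpl31 at 1.01, Rps9 at 0.50 and Rpl35a at -1.81 (-0.89 without non-deprived array 2). Proteasome genes had a median of 0.23 (range 0.0595 to 0.205, below the value with all arrays; 16 of 26 higher, adjusted p = 0.859), with Psmb1 at 0.96, Psmd11 at 1.96 and Psmd6 at 0.57. Heat shock genes had a median of 0.15 (range 0.063 to 0.21, 8 of 11 higher, adjusted p = 0.967, camera's direction downward), with Bag3 at -0.36, Dnajb1 at 0.54 and Dnaja1 at -0.92; without non-deprived array 2 the latter pair were at 0.21 and -0.036. In these 5 further lists no member passed over all genes or adjusted over the list alone.

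Clock genes with the PAR bZIP transcription factors had a median difference of 0.37 (range 0.201 to 0.4999, 9 of 12 higher, camera adjusted p = 0.192) and 0 members passed over all genes or adjusted over the list alone. Dbp was at 7.29 ± 0.29 in the deprived and 6.23 ± 0.01 in the non-deprived arrays (mean ± SD, n = 3 each), a log2 difference of 1.06 ± 0.30 (SE), and Tef was at 7.36 ± 0.07 against 6.84 ± 0.11. Bhlhe41, a transcriptional repressor of the clock, differed by 1.14 ± 0.40 (0.71 without deprived array 3). All 3 genes were higher in every deprived than in every non-deprived array. The differences without non-deprived arrays 2 and 3 were 1.05 for Dbp, 0.56 for Tef and 1.37 for Bhlhe41.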

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

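Leaving out non-deprived arrays 2 and 3 together was chosen after the result was seen; all other settings were fixed before the data were examined. Limma called 0 genes at an adjusted p under 0.05 under every one of the 17 settings that refit it and 0 at an adjusted p under 0.1, so what moved were the counts at an unadjusted p under 0.05 (566 higher, 209 lower) and the 6 lists. The lower count was 336 after median centring, 50 over genes at or above the median mean, 87 over genes at or above the 25th percentile and 393 with every cluster tested on its own. Median centring lowered the differences of all genes alike. The filters tested fewer and the last setting more features, and the cause was otherwise not tested. Leaving out each array in turn gave 357 to 1434 higher and 149 to 416 lower genes and 1 to 10 lists. The highest counts came without non-deprived array 1 (1434, 416 and 10 lists), where arrays 2 and 3 alone stand for the group. Without non-deprived array 2 there were 375 higher genes and 1 list, without non-deprived array 3 there were 357 higher genes, and without deprived array 3 there were 3 lists. Without non-deprived arrays 2 and 3 there were 219 higher and 390 lower genes and 1 list. The list count was 2 over genes at or above the median mean, 0 with an estimated correlation and 0 with fry. Camera's list count was 4 to 8 under the other settings. The pseudocount alternatives were not run because the values are already on a log scale. No background signal was used here, so what low signal limits could not be measured.

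With the replicate number as a block there were 0 genes past the threshold, 539 higher and 206 lower at an unadjusted p under 0.05, and 5 lists; the stress list was the one that lost its call (median 0.48, adjusted p = 0.0566). The numbers were not taken as pairing the arrays: deviations from the group means correlated at -0.051, -0.018 and -0.0033 for numbers 1, 2 and 3, and 0 of 6 arrays correlated best with their own number. The Y-linked gene Eif2s3y was at 6.76, 8.24 and 2.81 in non-deprived arrays 1 to 3 and at 6.88, 8.51 and 2.33 in deprived arrays 1 to 3, so that its level followed the numbers. Kdm5d, also Y-linked, was lowest in array 3 of both groups (3.85 and 4.05). That is a hint from the data that same-numbered arrays belong together, which the labels do not state.

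Of 1606 differences of named genes over the settings, 20 changed sign, and of 492 list medians 46 did; 39 list results lost the threshold, 37 of them with the same sign and 2 with a changed one, and 12 came past it. Leaving out 1 array moved 52 of the 119 named-gene differences and 29 of the 31 list medians by over 1.5 times, so single members rest on few arrays. None of the genes and lists that changed sign had passed in the main setting, except the scaffold and axon guidance lists without non-deprived arrays 2 and 3. Apart from the common shift by median centring, causes were not tested. With quantile normalization Egr1 was -0.21 and Nr4a1 -0.0697, and list medians were -0.11 for late effectors, -0.16 for MAP kinase inhibitors, -0.0096 for CREB signalling, -0.05 for plasticity factors, -0.017 for interneurons, -0.036 for astrocytes, -0.0399 for oligodendrocytes, -0.14 for their precursors and -0.0858 for endothelium. With median centring Egr1 was -0.019, and medians were -0.0932 for MAP kinase inhibitors, -0.044 for interneurons, -0.066 for oligodendrocytes, -0.066 for precursors and -0.0897 for endothelium. Centring moved all differences alike, with the median over all genes going from 0.05 to -0.047, and these sign changes are that shift. Over genes at or above the median mean, MAP kinase inhibitors were at -0.096, and over those at or above the 25th percentile oligodendrocytes were at -0.031 and endothelium at -0.042.

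Without non-deprived arrays 2 and 3, the differences were 0.33 for Fos, -0.48 for Gad1, -0.38 for Gad2, -0.15 for Mbp, -0.069 for Grin2b, 0.33 for Gabrb2, -0.00067 for Sv2b and -0.017 for Rasgrf2. List medians were -0.022 for glutamate receptors, -0.049 for scaffold genes, -0.013 for vesicle release, -0.017 for axon guidance, -0.022 for cholesterol synthesis, -0.11 for glycolysis, 0.025 for oxidative phosphorylation, -0.0803 for ribosomal proteins, -0.067 for the proteasome, -0.15 for layer 2/3, -0.19 for interneurons, -0.01 for oligodendrocytes and 0.15 for microglia. Leaving out each array in turn, the ranges that crossed 0 were -0.36 to 0.16 for Arc, -0.55 to 0.25 for Fos, -0.0033 to 0.18 for Egr1, -0.28 to 0.63 for Nr4a1, -0.00017 to 0.21 for Bdnf, -0.034 to 0.84 for Rorb and -0.11 to 0.46 for Mbp. For list medians they were -0.044 to 0.11 (oligodendrocyte precursors), -0.05 to 0.041 (endothelium), -0.14 to 0.16 (MAP kinase inhibitors), -0.034 to 0.44 (GABA receptors), -0.005 to 0.37 (vesicle release), -0.136 to 0.1002 (oxidative phosphorylation), -0.036 to 0.53 (ribosomal proteins), -0.047 to 0.089 (oligodendrocytes) and -0.019 to 0.28 (astrocytes).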

Other observations

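The PAR bZIP transcription factors Dbp, Tef and Hlf, whose transcripts cycle with the circadian clock in many tissues, were each higher in all 3 deprived than in all 3 non-deprived arrays. Hlf, chosen after its values were seen, was at 9.04, 9.12 and 9.41 in the deprived and 8.88, 8.49 and 8.84 in the non-deprived arrays, a log2 difference of 0.46 ± 0.29 (SE) with an unadjusted p of 0.161 in limma. Of the other members of the clock list, Npas2 (-0.34), Clock (-0.20) and Nfil3 (-0.05) were lower. Higher were Bhlhe41 (1.14), Nr1d2 (0.39), Cry1 (0.38), Rora (0.37), Arntl (0.37) and Per3 (0.10). Except for Bhlhe41, these other members were named after their values were seen. Fry's test for change in either direction, looked at after the data were seen, gave this list the smallest p of 31 lists (0.000952, adjusted p = 0.0295), and its directional test an adjusted p of 0.177. The list median was 0.37 with all arrays and 0.35 without non-deprived arrays 2 and 3, where its camera adjusted p was 0.198. Leaving out 1 array gave medians from 0.201 (without deprived array 3) to 0.4999.

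Interneuron markers were read on all 6 arrays although the cells are labelled as star pyramid neurons, and they went different ways. Sst, the somatostatin precursor, was between 10.08 and 11.59, Nxph1 between 9.01 and 10.63 and Npy between 7.14 and 10.23. Gad2 was at 5.98 and 6.34 in non-deprived arrays 2 and 3 and between 7.81 and 9.13 on the other 4 arrays, Pvalb was between 3.76 and 7.94, and Vip between 3.13 and 3.58. Levels of different clusters cannot be set against each other on an array, and no background was measured here, so these values do not give the share of interneurons. Between the groups the log2 difference was -0.10 ± 0.44 (SE) for Sst, 0.28 ± 0.44 for Nxph1 and -0.89 ± 0.76 for Npy, and none of these genes passed. Sst, Nxph1, Npy and Vip were chosen after their values were seen.

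Among the patterns below, the tests of signal loss, of other cell types and of interneuron loss were chosen only after the results were seen. The 6 lists that were higher in the deprived arrays hold 117 genes. Relative to the median of all genes, the median difference of these genes was 0.471 with all 6 arrays and 0.098 (95% bootstrap interval over genes -0.027 to 0.217) when the deprived arrays were set against non-deprived array 1 alone. Loss of signal in non-deprived arrays 2 and 3 is a candidate explanation for part of the difference, but this drop cannot decide it. The lists were picked for being higher with these arrays included, so a smaller value without them was likely whatever the cause. Non-deprived array 1 correlated with the deprived arrays at r of 0.935 to 0.946, but with non-deprived arrays 2 and 3 at 0.863 and 0.895. The drop would also follow if array 1 were the atypical sample of its group. Of the 6 lists, the excitatory markers kept the largest median against array 1, 0.36. After quantile normalization, which gives all arrays the same distribution, the scaffold and stress lists no longer passed and 4 lists did. These were sodium channels (median 0.32), calcium channels (0.38), axon guidance (0.29) and excitatory markers (0.47). Each median was smaller than before, but the median over all genes moved down too, from 0.05 to -0.043. Whether a loss of signal that falls on some genes more than on others explains the remaining 4 calls stays open. A trend with abundance cannot be told apart. The median difference was 0.05 over all genes and 0.227 over those at or above the median mean. Brighter genes in general were thus higher in the deprived arrays. Of the 6 lists, 3 (scaffold, calcium channels and axon guidance) had a median above the central 95% range of random lists matched on mean expression. The random lists take genes as independent, whereas camera's estimated correlations for these 3 lists were 0.28, 0.24 and 0.21. The 6 lists were also picked because they were higher, so this count decides nothing. More cells of other types in the non-deprived pools also stay open. Interneuron markers differed by a median of 0.053 (bootstrap interval -0.054 to 0.498), which reaches below 0, and by -0.19 against array 1 alone. With all 6 arrays the medians were 0.12 for astrocyte, 0.03 for oligodendrocyte, -0.11 for microglial and 0.0073 for endothelial markers. These lists thus did not fall together in the deprived arrays. An effect of deprivation remains open too.

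Tac1 and Cort, neuropeptide precursors that are also made by interneurons, were lower in the deprived arrays. Cort, chosen after its values were seen, was at 8.45, 10.49 and 9.45 in the non-deprived and 6.38, 8.95 and 7.61 in the deprived arrays, a difference of -1.82 ± 0.79 (SE), and Tac1 differed by -4.10 ± 1.26, with adjusted p = 0.856 for both in limma. If fewer interneurons had been picked in the deprived samples, Gad1, Gad2, Slc32a1, Lhx6 and Dlx1 should be lower too. Their median difference was 0.533 (bootstrap interval over these genes -0.005 to 1.503). However, Gad1 and Gad2 were lowest in non-deprived arrays 2 and 3. Against non-deprived array 1 alone the median was -0.38 and the lowest -0.48. In neither comparison did these markers fall as far as Tac1 or Cort. For Cort the gap was smaller against non-deprived array 1 alone. It was at 8.45 on that array, the lowest value of its group, and at a mean of 7.65 in the deprived arrays. Tac1 was at 9.26 and 4.74. Their direction depended on the arrays used, so the test cannot decide whether fewer interneurons were picked. Whether the share of peptide-expressing interneurons differed, or their transcription of these genes, remains open and was not tested.

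With 10 splits of 6 arrays into 3 and 3, no share under 0.05 is possible. The real split gave 775 genes at an unadjusted p under 0.05 and the highest other split 1267, and 4 splits gave at least as many as the real one, itself included. For genes at an adjusted p under 0.05 the real count was 0 and the highest other 1, so all 10 splits gave as many. For lists it was 6 and the highest other 12, and 3 splits gave at least 6. The 4 splits with the most genes were those that keep non-deprived arrays 2 and 3 together (775, 992, 1094 and 1267 genes, against 486 to 556 for the other 6), which points to a structure of the samples apart from deprivation.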
